A study of Homo sapiens with 9 samples.

How the data were processed

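RNA was sequenced from HaCaT cells on day 3 of culture, in 9 libraries from 3 groups of 3, named Ti, pdna and blank by the labels, with replicate numbers from the same labels. The series design names coated specimens carrying a LAMA3 plasmid in ZIF-8 as the experimental group and pure titanium as the control. The group labelled pdna was taken as the coated specimens, and what blank stands for is not given in the sources used here.

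The authors deposited a table of gene counts, whole numbers that are not normalized, with 1 column per library. A second deposited table gives FPKM values, which the authors scaled per kilobase and per sequenced fragment total. The submitters' processing notes name HISAT2, StringTie and GRCh38. Their roles and versions, the annotation release, the strand setting and how whole counts were obtained are not given in the sources used here, so antisense or overlapping genes and near-identical copies are uncertain. The count table has 24596 rows, of which 4622 are named NewGene and carry no Ensembl ID. These took 1.46% to 1.95% of the counts of a library and were left out of library sizes and tests. Of the 19974 rows with an Ensembl ID, 19883 matched the table of gene names used.

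Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM factors, filterByExpr by group, which left 13554 genes, and 1 fit of all 9 libraries with a mean per group, without robust hyperparameters. P-values were adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05. Comparisons were pdna against Ti, pdna against blank and Ti against blank. CPM values use TMM library sizes, and means carry the SD of 3 libraries. Log2 fold changes carry a standard error (SE), computed as their absolute value over the square root of the quasi-likelihood F statistic. With 3 libraries against 3, an exact permutation test cannot give a p below 0.1.

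Of 39 gene lists, 38 had at least 4 tested members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The tests were repeated with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Beside each count over all genes, members were adjusted over the list alone. The groups, tests, lists, alternatives and rule for named genes were fixed before the data were examined.

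The rule names every measured member of the laminin-332 and metallothionein lists, and a few genes it names are not reported here. It also names, in each comparison, the 7 genes of largest log2 fold change each way among those at adjusted p under 0.05, with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups. From the 12 lists of smallest camera p it takes the 3 members of smallest p that pass in pdna against Ti, and 2 in the comparisons with blank. The highest-expressed member of a list may be named too. After the data were seen, the rule was applied also to the fit of 7 libraries described next, and genes named outside it are marked where they appear.

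Replicate 3 of pdna and replicate 3 of blank stood apart from their groups, and each result was computed also without both, with sample weights in limma-voom, with a GC trend removed per library and with the mean level of the hypoxia and glycolysis list as a covariate. These alternatives, the robust and bias-adjusted versions of edgeR and the inclusion of NewGene rows were added after the data were seen. Transcript GC content and length, and the coordinates given, come from GENCODE release 29 on GRCh38. Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, other size factors, no filter or a CPM of at least 1 in 3 libraries, log2 of FPKM with a pseudocount of 1 or 0.1, a fit of the compared groups alone, a fold threshold of 1.5, a minimum log2 fold change of 1, the replicate number as a block, and leaving out each library in turn.

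Whether the replicate numbers pair libraries was checked by the correlation, across genes, of deviations from group means. Same-numbered pdna and blank libraries correlated at 0.40, 0.26 and 0.59, each above 0.1, so the blocked value is given beside results of that pair where it changes a call. The pairs with other numbers, pdna replicate 1 with blank replicate 2 and pdna replicate 2 with blank replicate 1, had similar values of 0.34 and 0.27, and same-numbered pairs with Ti had -0.083 to 0.027.

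The procedure was tested on simulated data for pdna against Ti, with 200 changed genes in each of 5 draws. With 9 libraries it recovered 34.7% of genes changed 2-fold and 84.4% of those changed 4-fold, with 4.98% false calls. With 7 libraries the values were 73.5%, 89.1% and 8.38%. Each gene was drawn on its own, without trends that run through a library, so these rates may not hold for the real libraries. Total counts of 34622712 to 42624333 per library set the precision of counting, and the spread between libraries was the larger limit, with a common dispersion of 0.0695 in 9 libraries and 0.0165 in 7.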

Results

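The series profiled the transcriptome of HaCaT cells, an immortalised human epidermal keratinocyte line, after 3 days of culture. There were 9 poly-A RNA-seq libraries in 3 groups of 3. Titanium (Ti) was the bare metal that the series design names as the control. The libraries labelled pdna were taken as the cells grown on the coating, which carries a plasmid encoding LAMA3 inside ZIF-8, a zinc-based metal-organic framework. The labels do not say what the group called blank was. Total counts per library ranged from 34622712 to 42624333, and 13554 genes had enough counts to be tested. Nothing in the labels says that the replicates were separate cultures, so every p-value here measures only the spread between these libraries, which may be technical.

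Libraries within a group were not equally alike. Replicate 3 of pdna and replicate 3 of blank stood apart from the others on the first principal component, which held 40.0% of the variance, at 35.3 and 83.7 against -32.5 to -5.22 in the other libraries. In both, counts followed the GC content of the transcript. Across genes, which are not independent replicates, the deviation of blank replicate 3 from the other libraries of its group had a Spearman correlation of -0.80 with GC content, and that of pdna replicate 3 had -0.61. The correlations had the opposite sign in the other libraries of these groups, 0.77 and 0.65 in blank replicates 1 and 2 and 0.58 and 0.42 in pdna replicates 1 and 2, each set against a pair that includes replicate 3. Those in the Ti libraries lay between -0.13 and 0.068. With genes ordered into 10 bins by GC content, the median deviation of blank replicate 3 was 0.82 in the lowest bin and -1.34 in the highest. The hypoxia and glycolysis list was also higher in these libraries. Its mean log2 level relative to all libraries was 0.86 in pdna replicate 3 and 0.14 in blank replicate 3, against -0.96 to -0.81 in the other pdna and blank libraries and 0.77 to 0.97 in Ti. Each count of changed genes below is therefore also given for the 7 libraries without this pair, an alternative chosen after the data were seen.

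**Figure D1:**
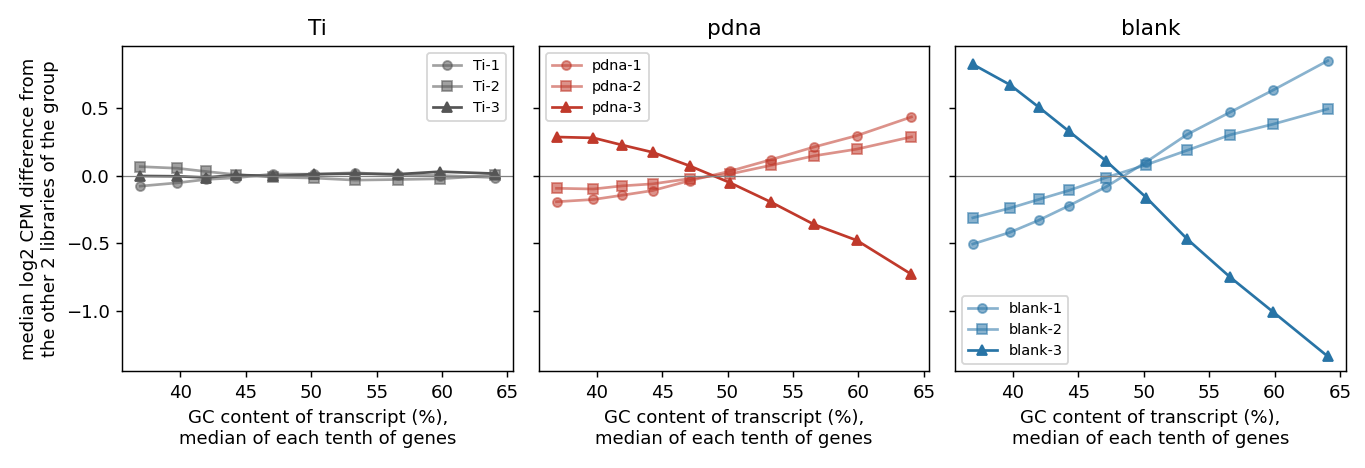
Median log2 CPM difference of each library from the other 2 of its group (vertical axis) over 10 bins of genes ordered by the GC content of the transcript (horizontal axis, percent), with a panel per group and a line per library. The lines of pdna replicate 3 and blank replicate 3 fall from 0.29 and 0.82 in the lowest bin to -0.73 and -1.34 in the highest, while those of the Ti libraries stay between -0.076 and 0.068.

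The comparison of pdna with Ti is the one the series design names, coated specimens against pure titanium. LAMA3, the laminin alpha-3 chain that the plasmid carries (ENSG00000053747, GRCh38 chromosome 18, 23689443 to 23956222, plus strand), was read first as a check of the labels. Its level was 416 ± 93.6 CPM (SD, n = 3) in the libraries labelled pdna and 635 ± 17.2 CPM in those labelled Ti. This is a log2 fold change of -0.61 (SE 0.16), with every pdna library below every Ti library, which chance gives in 10% of comparisons of 3 against 3 in either direction. The direction is against what the labels would lead one to look for, so the directions below are those between libraries as labelled. The difference did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.592), and passed it in the 7 libraries (-0.81, adjusted p = 8.47e-05). The count table has 1 row for LAMA3 and cannot separate plasmid from endogenous transcripts.

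Genes of the type I interferon response, the antiviral programme downstream of the interferon receptor, rose as a group in the libraries labelled pdna: 30 of 31 members lay above 0, with a median log2 fold change of 0.60 (camera, adjusted p = 7.0e-29, and adjusted p = 0.00223 with an estimated correlation). The genes of the TGF-beta and mesenchymal list fell as a group, with 15 of 18 members below 0 and a median of -0.49 (adjusted p = 3.6e-14, and adjusted p = 0.00577 with an estimated correlation). The laminin-332 and hemidesmosome list, the anchoring structures by which basal keratinocytes hold to the basement membrane, fell with all 9 members below 0, or 8 of 9 with library size alone, where ITGA6 had 0.025, and a median of -0.49 (adjusted p = 2.3e-09, but adjusted p = 0.0717 with an estimated correlation). No single gene passed over all 13554 genes: edgeR's quasi-likelihood test called 0 genes with 559 at an unadjusted p under 0.05, DESeq2 called 64 and limma-voom 1. In the 7 libraries edgeR called 929 genes, 333 higher and 596 lower in pdna.

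Among the interferon genes, 0 of 31 passed over all genes and 12 were higher when adjusted over the list alone. In the 7 libraries 14 passed over all genes as higher. OAS2, an antiviral oligoadenylate synthetase, had 46.9 ± 0.842 CPM in pdna and 21.1 ± 1.89 CPM in Ti (log2 fold change 1.15, SE 0.16). The values for OASL and DDX60 were 1.23 (SE 0.25) and 1.29 (SE 0.24), those for IFI44 and BST2 were 1.05 (SE 0.23) and 1.52 (SE 0.33), and RSAD2, which encodes the antiviral enzyme viperin, had 1.94 (SE 0.41). CD74, the invariant chain of MHC class II, had the smallest p of all genes, with 17.7 ± 2.72 CPM in pdna and 5.87 ± 0.601 CPM in Ti (1.59, SE 0.18, adjusted p = 0.0651). In the 7 libraries it passed edgeR's quasi-likelihood test (adjusted p = 3.00e-05). CD74 is not on the interferon list. It was also lower in Ti than in blank (-1.68, SE 0.18) and did not pass in pdna against blank.

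Of the 9 laminin-332 and hemidesmosome genes, 0 passed over all genes and 4 were lower when adjusted over the list alone. LAMB3, the beta-3 chain of laminin-332, had a log2 fold change of -0.45 (SE 0.22), and COL17A1, a transmembrane collagen of the hemidesmosome, had -0.62 (SE 0.18). The tetraspanin CD151 had -0.68 (SE 0.22). Other members were ITGB4 at -0.49 (SE 0.29), PLEC at -0.32 (SE 0.30), DST at -0.24 (SE 0.17) and ITGA6 at -0.016 (SE 0.25). In the TGF-beta and mesenchymal list 4 of 18 were lower when adjusted over the list alone and 0 over all genes. Among its members, FN1, which encodes fibronectin, had 91.5 ± 10.6 CPM in pdna and 284 ± 67.6 CPM in Ti (-1.63, SE 0.23). FN1 lies outside the rule for named genes in this contrast and was chosen after its values were seen. PMEPA1, a TGF-beta target, had -1.69 (SE 0.23) and LOXL2, a collagen cross-linking enzyme, had -1.40 (SE 0.38).

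**Figure D2:**
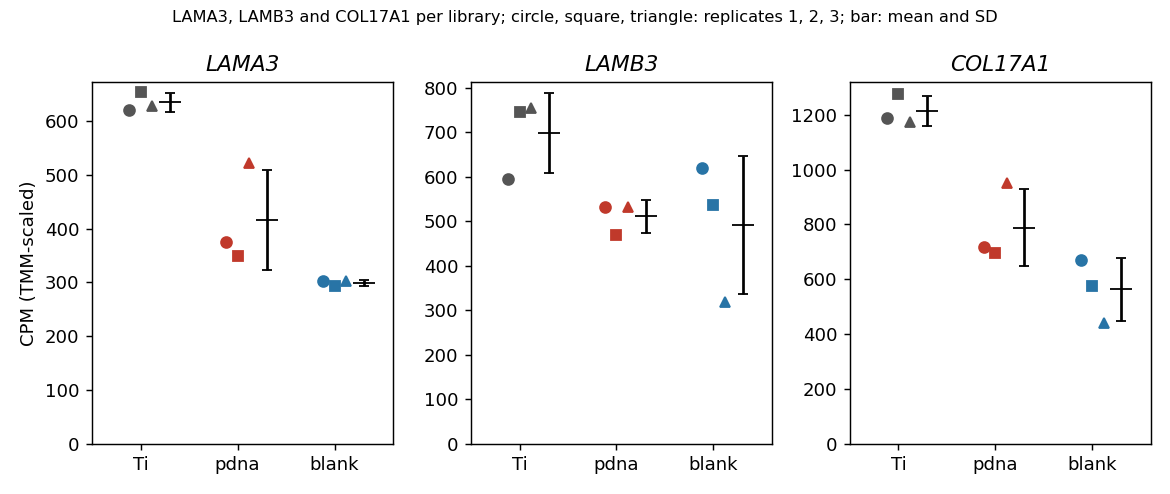
CPM (vertical axis) of LAMA3, LAMB3 and COL17A1 in each library of the Ti, pdna and blank groups, with bars at the mean and SD of 3 libraries. Circles, squares and triangles are replicates 1, 2 and 3. The LAMA3 means are 635 CPM in Ti, 416 CPM in pdna and 299.6 CPM in blank.

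The hypoxia and glycolysis list, targets of the oxygen-sensing HIF pathway, fell with all 25 members below 0 and a median log2 fold change of -0.69 (camera, adjusted p = 2.8e-21, but adjusted p = 0.19 with an estimated correlation). This list moved with the libraries that stand apart: its median was -1.37 in the 7 libraries, where 24 of 25 members passed over all genes. ANGPTL4, a secreted inhibitor of lipoprotein lipase, had -1.89 (SE 1.24) with 9 libraries and -5.47 (SE 0.19) with 7, and CA9, a carbonic anhydrase, had -1.49 (SE 1.04) and -3.88 (SE 0.24). With 9 libraries NDRG1 had -1.53 (SE 0.92), EGLN3 -0.83 (SE 1.10), BNIP3 -1.05 (SE 0.83) and LDHA, lactate dehydrogenase, -0.69 (SE 0.52). Without pdna replicate 3 these had -3.66, -3.42, -2.76 and -1.62. The metallothionein and zinc export list, genes that bind or export zinc, fell with all 5 tested members below 0 and a median of -0.96 (adjusted p = 6.3e-06, but adjusted p = 0.19 with an estimated correlation). It also moved with the libraries that stand apart: its mean log2 level was 0.50 in pdna replicate 3 and 0.50 to 0.89 in Ti, against -0.73 and -0.71 in the other pdna libraries, and without pdna replicate 3 its median was -1.63. MT2A, a metallothionein, had 54.4 ± 27.4 CPM in pdna and 122 ± 20.2 CPM in Ti (-1.16, SE 0.34), MT1E had -0.96 (SE 0.46), MT1F -1.01 (SE 0.30), MT1X -0.83 (SE 0.70) and the zinc exporter SLC30A1 -0.19 (SE 0.45). Over all genes 0 of the 5 passed, and 2 were lower when adjusted over the list alone. With the mean level of the hypoxia and glycolysis list as a covariate, the metallothionein median came to -0.044 and the list did not pass camera (adjusted p = 0.976). That level was 0.77 to 0.97 in Ti and -0.87 and -0.96 in pdna replicates 1 and 2. This fit therefore cannot separate it from the group.

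**Figure D3:**
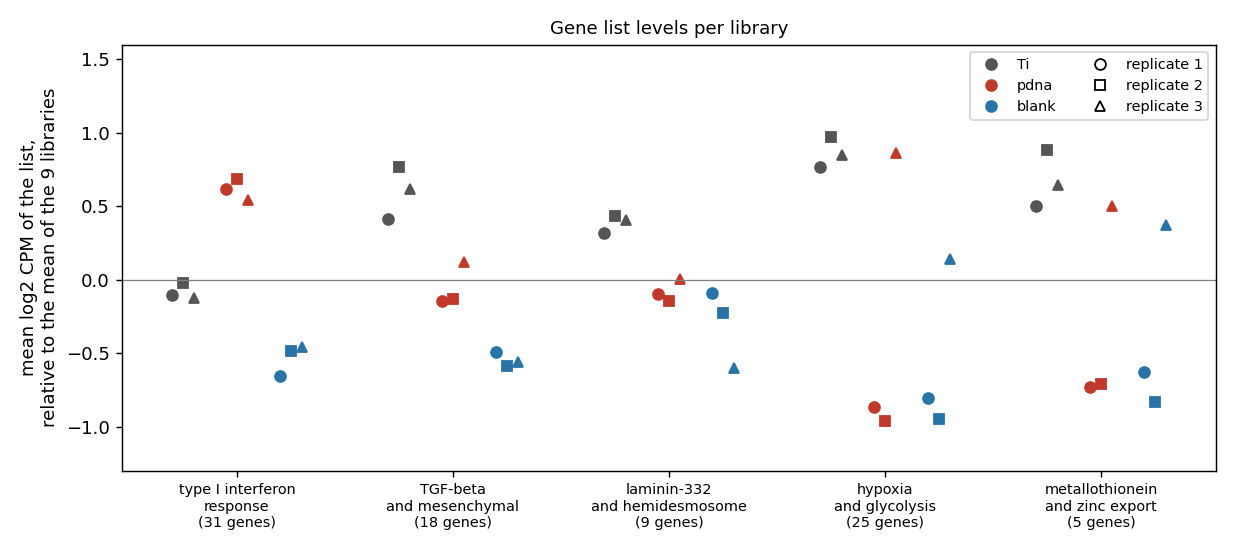
Mean log2 CPM of 5 gene lists in each library relative to the mean of the 9 libraries (vertical axis), by list (horizontal axis), coloured by group with a symbol per replicate. On the hypoxia and glycolysis list pdna replicate 3 lies at 0.86, beside the Ti libraries, while the other pdna libraries lie at -0.87 and -0.96.

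In this comparison 18 of 38 tested lists passed, 3 higher and 15 lower in pdna. A split of the same libraries that grouped pdna replicates 1 and 2 with Ti replicate 2 passed 19. The number of passing lists alone therefore does not mark a difference between the groups. Of the 18, 2 lists, the interferon and the TGF-beta and mesenchymal lists, also passed with an estimated correlation. In the 7 libraries the second of these lost that call (adjusted p = 0.0767 with an estimated correlation) with a median of -0.53 (SD over members 0.94, against 0.67 in 9 libraries), while the estimated correlation of its genes went from 0.019 to 0.20. The interferon list kept the call (adjusted p = 0.0412) and the hypoxia list gained it (adjusted p = 0.0131). The other lists that fell are given with their medians and their adjusted p with an estimated correlation. Those of structure and adhesion were integrin and focal adhesion -0.13 (adjusted p = 0.19), matrix protease and inhibitor -0.24 (adjusted p = 0.0717), simple epithelial keratin -0.28 (adjusted p = 0.19), and desmosome and adherens junction -0.085 (adjusted p = 0.559). Keratinocyte differentiation and cornified envelope had -0.24 (adjusted p = 0.285) and basal keratinocyte -0.34 (adjusted p = 0.322). The mean log2 level of the first of these was 0.31 in pdna replicate 3, inside the range of 0.26 to 0.34 in Ti, against -0.52 and -0.43 in the other pdna libraries. Immediate-early had -0.40 (adjusted p = 0.19), inflammatory cytokine and NF-kB -0.27 (adjusted p = 0.322) and antimicrobial peptide -0.33 (adjusted p = 0.308). Ribosomal protein had -0.19 (adjusted p = 0.377) and DNA replication -0.12 (adjusted p = 0.668). The NRF2 oxidative stress list rose with a median of 0.18 (adjusted p = 0.322) and the cholesterol synthesis list with 0.073 (adjusted p = 0.471). Adjusted over each list alone, 1 simple epithelial keratin was lower, 1 cholesterol gene was higher, and 1 matrix protease gene was higher and 2 lower. In the ribosomal, immediate-early, integrin, cornified envelope, inflammatory, antimicrobial, DNA replication, basal keratinocyte, desmosome and NRF2 lists 0 passed. None of these members passed over all genes. The lists that did not pass had medians from -0.24 to 0.13, among them cytosolic DNA sensing (0.082), zinc import (-0.050), unfolded protein response (-0.060) and leukocyte markers (-0.24).

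Named members of these lists gave the following log2 fold changes of pdna over Ti with 9 libraries, none passing over all genes. The aldo-keto reductase AKR1B10 had 1.40 (SE 0.41) and TXNRD1 0.33 (SE 0.14). In cholesterol synthesis, HMGCS1 had 0.62 (SE 0.13), INSIG1 0.41 (SE 0.25) and FDFT1 0.22 (SE 0.19). The proteases MMP7, MMP13 and PLAT had -0.92 (SE 0.47), -1.20 (SE 0.30) and -0.59 (SE 0.13). CASP14, a caspase of terminal differentiation, had -2.58 (SE 1.73), TGM5 -0.96 (SE 0.50) and SPRR2D -2.59 (SE 1.06). These values rest on pdna replicate 3: CASP14 had 0 CPM in pdna replicates 1 and 2 and 5.86 CPM in replicate 3, against 10.8 to 12.6 CPM in Ti, and SPRR2D had 0, 0 and 0.268 CPM against 0.414 to 0.582 CPM, so no fold is given without that library. TGM5 had -1.81 without it. With 1 library left out 22 of the 54 genes named in this comparison moved by over 1.5 times, 20 of them without pdna replicate 3. The immediate-early genes FOS, KLF6 and IER3 had -0.92 (SE 0.50), -0.20 (SE 0.28) and -0.66 (SE 0.34). Of the adhesion genes, NECTIN1 had -0.43 (SE 0.19), CDH3 -0.35 (SE 0.16) and DSG3 -0.11 (SE 0.33), and of the ribosomal protein genes, RPL23 had -0.29 (SE 0.22), RPLP0 -0.30 (SE 0.11) and RPS19 -0.34 (SE 0.17). TCAF2 and P2RX5-TAX1BP3, a read-through locus that shares reads with its neighbours, had -0.97 (SE 0.84) and 1.61 (SE 0.74).

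The count of changed genes was 1 without Ti replicate 3, 15 without pdna replicate 3 and 50 without blank replicate 3, and 15 with the GC trend of each library removed, all 15 of them also called in the 7 libraries. Leaving out 1 library ended the calls of the desmosome list (without Ti replicates 2 or 3, pdna replicates 1 or 2, or blank replicate 2, adjusted p up to 0.410) and the basal keratinocyte list (Ti replicate 3 or pdna replicate 2, up to 0.211). It also ended those of the antimicrobial (Ti replicate 1 or pdna replicate 2, up to 0.123) and DNA replication lists (Ti replicate 1, pdna replicates 1 or 3, up to 0.973). The inflammatory list (Ti replicate 1, pdna replicates 1 or 3, up to 0.231) and the cholesterol list (Ti replicate 1 or pdna replicate 1, up to 0.280) lost theirs in the same way. The desmosome list also lost its call with the replicate number as a block (adjusted p = 0.0501). Removing the GC trend ended the calls of the simple epithelial keratin (median -0.20, adjusted p = 0.0542), cornified envelope (-0.16, adjusted p = 0.0772), cholesterol (0.056, adjusted p = 0.0772), antimicrobial (-0.23, adjusted p = 0.0772) and basal keratinocyte lists (-0.23, adjusted p = 0.0906). The antimicrobial (-0.60, adjusted p = 0.0535) and DNA replication lists (-0.095, adjusted p = 0.323) did not pass in the 7 libraries. Of 18 medians of passing lists 13 lay more than 1.5 times above or below their value in 9 libraries at the lowest or highest value with 1 library left out. Without Ti replicate 1 they were DNA replication 0.0065, antimicrobial -0.13, cholesterol -0.018 and inflammatory -0.094. Without Ti replicate 2 it was antimicrobial -0.63. Without Ti replicate 3 it was DNA replication -0.19. Without pdna replicate 1 they were NRF2 0.12 and cornified envelope -0.14. Without pdna replicate 2 they were basal keratinocyte -0.21, desmosome -0.0062 and ribosomal protein -0.12. Without pdna replicate 3 they were cholesterol 0.19, desmosome -0.23, hypoxia -1.37, integrin -0.081, cornified envelope -0.53, matrix protease -0.39 and metallothionein -1.63.

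The comparison of pdna with blank set the coated group beside the third labelled group, whose meaning is not given in the sources used here. Interferon genes rose in the libraries labelled pdna: 30 of 31 members lay above 0, with a median log2 fold change of 0.86 (camera, adjusted p = 8.1e-70, and adjusted p = 0.000141 with an estimated correlation). RSAD2 had 28.4 ± 2.96 CPM in pdna and 3.27 ± 1.42 CPM in blank (n = 3 each), a fold of 8.70 (log2 3.12, SE 0.43, adjusted p = 0.0395 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). KRT4, a keratin of mucosal epithelium, fell by 1.72 on the log2 scale (SE 0.20, adjusted p = 0.0230), from 355 ± 34.4 CPM in blank to 108 ± 22.3 CPM in pdna. Over all 13554 genes 11 changed, 8 higher and 3 lower in pdna, with 487 at an unadjusted p under 0.05. LAMA3 had 299.6 ± 5.92 CPM in blank, a log2 fold change of 0.47 (SE 0.16) that did not pass (adjusted p = 0.968).

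The 8 genes that rose were RSAD2, OASL (2.17, SE 0.26), DDX60 (1.92, SE 0.24), OAS2 (1.62, SE 0.16), IFI27 (2.78, SE 0.34), PLCG2, a phospholipase of immune receptor signalling (2.70, SE 0.24), SPOCK1, a secreted proteoglycan (2.40, SE 0.22), and NT5E, the ecto-5-prime-nucleotidase CD73 (1.14, SE 0.14). IFI27, PLCG2 and SPOCK1 fall outside the rule for named genes, since their mean log2 CPM is under 3, and are named after their values were seen. With KRT4, the genes that fell were BPIFB1, a secreted protein of airway epithelium (-1.53, SE 0.20), and the transporter ABCA13 (-1.22, SE 0.16). In all 11, the 3 pdna and the 3 blank libraries did not overlap. The genes were selected by a test between these same libraries, so this adds no support. In the interferon list 4 of 31 members passed over all genes and 20 when adjusted over the list alone. Among the rest were IFI44 with 1.44 (SE 0.23), BST2 with 1.77 (SE 0.33) and DDX58, the RNA sensor RIG-I, with 1.25 (SE 0.22). With the replicate number as a block BST2 passed over all genes (1.81, adjusted p = 0.0324 by edgeR's quasi-likelihood test). The labels do not say that replicate numbers pair the pdna and blank libraries. Replicates 1 and 2 of these groups correlated about as much across unlike numbers (0.34 and 0.27) as across like ones (0.40 and 0.26). With the number as a block 17 genes were called, 10 of them among the 11, with BPIFB1 lost (adjusted p = 0.0509 by edgeR's quasi-likelihood test).

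The TGF-beta and mesenchymal list also rose in pdna over blank, with all 18 members above 0 and a median of 0.37 (adjusted p = 6.0e-06, and adjusted p = 0.0478 with an estimated correlation), though 0 members passed over all genes or over the list alone. The simple epithelial keratin list was called lower (adjusted p = 3.1e-05, but adjusted p = 0.0956 with an estimated correlation) with a median of 0.042 and a mean of -0.51, so that its median differs in sign from its mean and its test. Its median was -0.12 in the 7 libraries. Of 7 members 1, KRT4, fell over all genes and 2 when adjusted over the list alone. KRT13 had -0.67 (SE 0.15). The list as fixed includes KRT4 and KRT13, which are keratins of mucosal epithelium. With a median above 0, its call does not show a fall of simple epithelial keratins in general. In the laminin-332 and hemidesmosome list 6 of 9 members lay above 0 (median 0.056, adjusted p = 0.00210, but adjusted p = 0.245 with an estimated correlation, and a median of -0.070 with adjusted p = 0.487 in the 7 libraries), 0 passed over all genes and 1 over the list alone. COL17A1 had 0.48 (SE 0.18), while LAMB3, CD151, DST, ITGA6, ITGB4 and PLEC had values from -0.098 to 0.18. The metallothionein and zinc export list did not pass (median 0.056), and MT1E, MT1F, MT1X, MT2A and SLC30A1 lay between -0.080 and 0.46.

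Of 38 lists 17 passed, 11 higher and 6 lower in pdna, and the interferon and the TGF-beta and mesenchymal lists also passed with an estimated correlation. The TGF-beta and mesenchymal list lost that call in the 7 libraries (adjusted p = 0.393 with an estimated correlation) and with the GC trend removed (adjusted p = 0.122). Its median was 0.36 (SD over members 0.35) and 0.41 (SD 0.44) there, against 0.37 (SD 0.46) in 9 libraries, and the estimated correlation of its genes was 0.19 and 0.035 against 0.014. The others that rose were fatty acid synthesis (median 0.23, estimated-correlation adjusted p = 0.245), YAP and SRF targets (0.19, adjusted p = 0.27), cholesterol synthesis (0.16, adjusted p = 0.288) and lysosome and autophagy (0.16, adjusted p = 0.245). So did p53 targets and apoptosis (0.21, adjusted p = 0.0956), other basement membrane (0.19, adjusted p = 0.496), integrin and focal adhesion (0.088, adjusted p = 0.27), and hypoxia and glycolysis (0.29, adjusted p = 0.689). Those that fell were antimicrobial peptide (-0.76, adjusted p = 0.245), mitosis (-0.18, adjusted p = 0.496), fibroblast markers (-0.52, adjusted p = 0.142), DNA replication (-0.14, adjusted p = 0.528) and mitochondrially encoded (-0.063, adjusted p = 0.496). Over all genes 0 members of these passed, and over the list alone 2 p53 targets were higher and 1 fibroblast marker was lower. PMAIP1, the apoptosis gene NOXA, had 0.75 (SE 0.18). Other genes named by applying the rule to the 7 libraries, with their values in 9, were SCGB1A1, the club cell secretoglobin, with -2.33 (SE 0.43), OLFM4 with -1.47 (SE 0.25), and MMP13 with -1.47 (SE 0.31). PIGR, the receptor that carries IgA across epithelium, had -1.01 (SE 0.27), SNCAIP -1.20 (SE 0.26), RPL23 -0.49 (SE 0.22), MT-CO3 -0.22 (SE 0.11) and MT-ND6 -0.24 (SE 0.14). None of these passed over all genes. With the replicate number as a block SCGB1A1 (-2.39, adjusted p = 0.0124), OLFM4 (-1.47, adjusted p = 0.0278) and MMP13 (-1.42, adjusted p = 0.0320) passed by edgeR's quasi-likelihood test.

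The count of 11 was 0 with only these groups in the fit, 91 in the 7 libraries, 64 with DESeq2 and 40 with the GC trend removed. It was 6, 3, 5, 2, 0, 4, 3, 1 and 24 without Ti replicates 1 to 3, pdna replicates 1 to 3 and blank replicates 1 to 3 in turn. Since it was 0 without pdna replicate 2, no gene could be called in every one of these. Without pdna replicate 3 the hypoxia median was -0.46 (adjusted p = 0.000962). Leaving out 1 library ended the calls of the laminin-332 list (pdna replicate 3 or blank replicate 3, adjusted p up to 0.445) and the hypoxia list (blank replicates 1 or 2, up to 0.445). It ended those of the other basement membrane (median -0.035 without blank replicate 3), mitosis and cholesterol lists (pdna replicate 1 or blank replicate 3, up to 0.896). The integrin, YAP and SRF, fatty acid and lysosome lists lost theirs without blank replicate 3 (up to 0.633), and so did the antimicrobial list (without blank replicates 1 or 3, up to 0.146). Others were the DNA replication list (pdna replicates 1 or 3, blank replicates 1 or 2, up to 0.262), the mitochondrially encoded list (pdna replicate 1, blank replicates 1 or 2, up to 0.327) and the fibroblast list (Ti replicates 2 or 3, pdna replicates 1 or 3, or blank replicate 1, up to 0.237). Removing the GC trend ended the calls of the hypoxia (median 0.28, adjusted p = 0.128) and mitochondrially encoded lists (-0.077, adjusted p = 0.0977). Calls lost in the 7 libraries were those of the lysosome (0.083, adjusted p = 0.0950), laminin-332 (-0.070, adjusted p = 0.487), other basement membrane (0.083, adjusted p = 0.27), integrin (0.034, adjusted p = 0.0985) and hypoxia lists (-0.029, adjusted p = 0.443). Of 17 medians of passing lists 14 lay more than 1.5 times above or below their value in 9 libraries at the lowest or highest value with 1 library left out. Without pdna replicate 1 they were laminin-332 0.019 and p53 0.083. Without pdna replicate 3 they were DNA replication -0.051, antimicrobial -1.25, cholesterol 0.31, fatty acid 0.36 and hypoxia -0.46. Without blank replicate 1 they were antimicrobial -0.39, fibroblast -0.28, integrin 0.20, laminin-332 0.24, other basement membrane 0.43 and simple keratin 0.15. Without blank replicate 2 it was mitochondrially encoded -0.030. Without blank replicate 3 they were DNA replication -0.22, cholesterol 0.047, hypoxia 0.84, integrin 0.0017, lysosome 0.061, mitochondrially encoded -0.16, mitosis -0.0065, other basement membrane -0.035 and simple keratin -0.17. Of 38 named genes 16 moved by over 1.5 times, 10 of them without pdna replicate 3 and 13 without blank replicate 3.

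Ti was compared with blank to give the distance between the metal and the third group. The TGF-beta and mesenchymal list rose in Ti, with 17 of 18 members above 0 and a median log2 fold change of 0.74 (camera, adjusted p = 1.4e-20, and adjusted p = 0.00486 with an estimated correlation). FN1 had 284 ± 67.6 CPM in Ti and 61.2 ± 15.0 CPM in blank, a fold of 4.64 (log2 2.21, SE 0.24, n = 3 each, adjusted p = 0.00981 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The laminin-332 and hemidesmosome list rose with 8 of 9 members above 0 and a median of 0.51 (adjusted p = 1.6e-12, and adjusted p = 0.0466 with an estimated correlation). LAMA3 had a log2 fold change of 1.08 (SE 0.16) and narrowly missed the threshold (adjusted p = 0.0577). It passed in 13 other settings, with adjusted p from 1.72e-06 to 0.0492, and leaving out 1 library at a time gave 0.00785, without pdna replicate 3, to 0.343, without Ti replicate 2.

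Over all genes 11 changed, 9 higher and 2 lower in Ti, with 1229 at an unadjusted p under 0.05. Besides FN1, the genes that rose included PMEPA1 (2.04, SE 0.23), SPOCK1 (2.33, SE 0.22), MYADM, a myeloid-associated membrane protein (1.54, SE 0.20), NT5E (1.32, SE 0.14), FSTL3, a follistatin-like inhibitor of activin (1.24, SE 0.17), CDH13, T-cadherin (1.03, SE 0.15), and TGFBI, a TGF-beta-induced matrix protein (0.99, SE 0.13). SPOCK1 lies outside the rule and was named after its values were seen. KRT4 fell by 1.82 (SE 0.20) and CD74 fell by 1.68 (SE 0.18), and in all 11 the libraries of the groups did not overlap. In the TGF-beta and mesenchymal list 3 of 18 members passed over all genes and 9 when adjusted over the list alone. In the laminin-332 list 1 of 9 passed over all genes and 4 over the list alone. COL17A1 had 1.11 (SE 0.18), CD151 0.70 (SE 0.22), LAMB3 0.51 (SE 0.22) and ITGA6 -0.081 (SE 0.25).

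The interferon list rose in Ti over blank with a median of 0.25 and 24 of 31 members above 0 (adjusted p = 1.7e-05, and adjusted p = 0.0466 with an estimated correlation), with 0 members passing over all genes and 1 over the list alone. Without blank replicate 3 the median was 0.44. OASL had 0.94 (SE 0.25) and CMPK2 0.99 (SE 0.33). The matrix protease and inhibitor list rose with a median of 0.28 (adjusted p = 4.4e-05, and adjusted p = 0.0466 with an estimated correlation), with 2 of 17 members higher over the list alone and 0 over all genes. MMP7 and SERPINB2 had 0.28 (SE 0.46) and 0.12 (SE 0.43). The hypoxia and glycolysis list rose with all 25 members above 0 and a median of 0.98 (adjusted p = 3.5e-20, but adjusted p = 0.189 with an estimated correlation). Of its members 0 passed over all genes and 10 over the list alone, and in the 7 libraries 23 passed over all genes. ANGPTL4, CA9, NDRG1, BNIP3, EGLN3 and LDHA had values from 0.96 to 3.39 with 9 libraries, with SE from 0.52 to 1.33. The metallothionein and zinc export list rose with 5 of 5 members above 0 and a median of 0.88 (adjusted p = 0.000131, but adjusted p = 0.191 with an estimated correlation). Over all genes 0 of the 5 passed and over the list alone 2, with MT1X at 0.80 (SE 0.70), MT1E 0.88 (SE 0.46), MT1F 1.47 (SE 0.30), MT2A 1.22 (SE 0.34) and SLC30A1 0.27 (SE 0.45).

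Of 38 lists 20 passed, 18 higher and 2 lower in Ti, and 4 passed with an estimated correlation, those of the TGF-beta, laminin-332, interferon and matrix protease genes. In the 7 libraries all 4 lost that call (adjusted p with an estimated correlation 0.101, 0.109, 0.109 and 0.167 in this order), and the hypoxia list alone had it (adjusted p = 0.0225). Their medians were 0.68, 0.46, 0.44 and 0.30 there (SD over members 0.99, 0.47, 1.01 and 1.94), against 0.74, 0.51, 0.25 and 0.28 in 9 libraries (SD 0.93, 0.47, 1.00 and 1.94). The estimated correlations of their genes were 0.21, 0.30, 0.031 and 0.11, against 0.027, 0.17, 0.018 and 0.014. With the GC trend removed the TGF-beta list alone kept it (adjusted p = 0.0105), and the laminin-332, interferon and matrix protease lists had adjusted p = 0.124 each with an estimated correlation. These 3 then had medians of 0.49, 0.31 and 0.33 (SD 0.46, 0.99 and 1.92), with estimated correlations of 0.55, 0.069 and 0.12. Others that rose, with their medians and estimated-correlation adjusted p values, were integrin and focal adhesion (0.26, adjusted p = 0.0781), YAP and SRF targets (0.38, adjusted p = 0.191) and desmosome and adherens junction (0.15, adjusted p = 0.504). Immediate-early (0.29, adjusted p = 0.189), inflammatory cytokine and NF-kB (0.47, adjusted p = 0.191) and leukocyte markers (0.55, adjusted p = 0.189) rose too. So did lysosome and autophagy (0.21, adjusted p = 0.189), ribosomal protein (0.20, adjusted p = 0.512), fatty acid synthesis (0.14, adjusted p = 0.504) and replication-dependent histone (0.22, adjusted p = 0.622). The last that rose were other basement membrane (0.29, adjusted p = 0.504) and cornified envelope (0.26, adjusted p = 0.393). Fibroblast markers (-0.74, adjusted p = 0.189) and NRF2 oxidative stress (-0.097, adjusted p = 0.512) fell. Over all genes 0 of these members passed. Adjusted over each list alone, 5 YAP and SRF targets, 3 immediate-early, 3 inflammatory, 2 lysosome, 1 integrin, 1 leukocyte, 1 desmosome and 1 fatty acid synthesis gene were higher and 1 fibroblast marker was lower. Members named by applying the rule to the 7 libraries, with values in 9 and none passing there over all genes, were the integrins ITGA5 (2.12, SE 0.35) and ITGB5 (1.08, SE 0.29), TNFAIP3, an NF-kB feedback inhibitor (0.97, SE 0.16), and INHBA (1.94, SE 0.60). By the same rule TAGLN2 (0.73, SE 0.18), F3 (0.72, SE 0.34), IER3 (1.30, SE 0.35), FOS (0.81, SE 0.49), PTGS2 (0.35, SE 0.66), CDH3 (0.65, SE 0.16) and DSC2 (0.24, SE 0.34) are named. Among genes lower in Ti were AKR1B10 (-1.67, SE 0.42), ALDH3A1 (-1.56, SE 0.37), CYP4B1 (-2.11, SE 0.38), ATP6V1B1 (-1.86, SE 0.32) and ALPG (-1.22, SE 0.49).

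The count of 11 was 279 with DESeq2, 1705 in the 7 libraries and 345 with the GC trend removed. It was 0, 0, 3, 8, 7, 46, 4, 0 and 63 without Ti replicates 1 to 3, pdna replicates 1 to 3 and blank replicates 1 to 3 in turn. With the replicate number as a block 23 genes were called, all 11 among them. The leukocyte list lost its call under the block (adjusted p = 0.0668). Leaving out 1 library ended the calls of the other basement membrane list (blank replicate 3, adjusted p = 0.312) and of the leukocyte list (Ti replicate 3 or a blank replicate, up to 0.167). It ended those of the desmosome (Ti replicates 2 or 3, pdna replicate 3, blank replicates 1 or 2, up to 0.161) and cornified envelope lists (Ti replicate 3, blank replicates 1 or 2, up to 0.176). The NRF2 (Ti replicates 2 or 3, blank replicates 1 or 2, up to 0.274) and fatty acid lists (Ti replicates 2 or 3, pdna replicate 3 or blank replicate 3, up to 0.538) lost theirs. So did the histone (Ti replicates 2 or 3, pdna replicate 3, blank replicates 1 or 2, up to 0.436) and fibroblast lists (any Ti replicate, pdna replicates 1 or 3, blank replicates 1 or 2, up to 0.316). Removing the GC trend ended the calls of the cornified envelope (median 0.23, adjusted p = 0.245), leukocyte (0.48, adjusted p = 0.149) and histone lists (0.13, adjusted p = 0.12). Those lost in the 7 libraries were of the other basement membrane (0.21, adjusted p = 0.341), leukocyte (0.48, adjusted p = 0.255) and fatty acid lists (0.033, adjusted p = 0.839). Of 20 medians of passing lists 14 lay more than 1.5 times above or below their value in 9 libraries at the lowest or highest value with 1 library left out. Without Ti replicate 1 they were NRF2 -0.17 and inflammatory 0.21. Without Ti replicate 2 it was YAP and SRF 0.21. Without blank replicate 1 they were NRF2 -0.013, fatty acid 0.33, fibroblast -0.29 and immediate-early 0.52. Without blank replicate 2 they were desmosome 0.085, leukocyte 0.83 and histone 0.058. Without blank replicate 3 they were fatty acid 0.033, hypoxia 1.47, integrin 0.14, metallothionein 1.48, histone 0.52, ribosomal protein 0.13 and interferon 0.44. Of 50 named genes 18 moved by over 1.5 times, all 18 without blank replicate 3.

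There were 10 lists that passed in none of the 3 comparisons. Their medians in pdna against Ti were -0.0061 for tight junction, -0.17 for wound keratin and S100 alarmin, -0.0049 for heat shock, -0.060 for unfolded protein response and -0.0080 for EGFR ligand and ERK feedback. The others had -0.018 for nuclear oxidative phosphorylation, -0.050 for ATF4 amino acid response, -0.050 for zinc import, 0.082 for cytosolic DNA sensing and 0.10 for endothelial markers. Their medians lay between -0.14 and 0.16 in pdna against blank and between -0.11 and 0.14 in Ti against blank. Median, mean and test also differed in sign in lists that did not pass. These were simple epithelial keratin in Ti against blank (median 0.27, mean -0.20), heat shock, tight junction, endothelial and ATF4 in pdna against Ti, wound keratin, heat shock, endothelial and ribosomal protein in pdna against blank, and DNA replication in Ti against blank.

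The number of genes changed the same way in pdna against both Ti and blank was 0 with 9 libraries, since pdna against Ti called 0. It was 41 in the 7 libraries, 30 higher and 11 lower in pdna, with OAS2, OASL, DDX60, RSAD2, IFI44, BST2, IFI27, CMPK2 and PLCG2 among those higher, 13 with DESeq2, 12 without blank replicate 3 and 1 without pdna replicate 3. Independent lists of the same lengths would share 1.53 higher and 1.22 lower, and 20 simulations of unchanged groups around the same pdna libraries gave a mean of 0.65 and at most 2 in the 7 libraries. The pdna libraries are too few to be divided between the comparisons, so part of the excess may come from sharing them. The simulations drew each gene on its own, without trends that run through a library, so they may understate the overlap of unchanged groups.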

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

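The tests of GC content, of transcript length, of mislabelled or exchanged libraries, of coverage of the whole gene and of leukocyte markers, the covariate and the inclusion of unnamed loci were chosen only after the results they bear on, or the data, were seen. Rows of the count table without an Ensembl ID were not used in the comparisons. When they were included, 2 of 2376 such rows tested passed in Ti against blank by edgeR's quasi-likelihood test (smallest adjusted p = 0.0225, log2 fold change 2.02), a signal above that of the blank libraries in data outside the main measurement.

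The hypoxia and glycolysis list was higher in pdna replicate 3 and blank replicate 3 than in the other libraries of their groups. Removing the GC trend of pdna replicate 3 left 94.4% of the list's median deviation (bootstrap SD 11.2 percentage points, 24 of 25 members above 0), and removing the trend on transcript length left 99.8% (SD 4.78) there and 98.4% (SD 44.7) in blank replicate 3, which argues against those trends as the whole cause, narrowly for the last. For blank replicate 3 the GC trend cannot be told apart from a change in the list, since 96.0% was left with an SD of 135 and 18 of 25 members lay above 0. Both libraries being mislabelled Ti libraries is argued against by the interferon and mesenchymal lists, of which the farther one lay outside the Ti range by at least 6.11 SD of the Ti libraries. The design names no difference between replicates of a group, and no biological explanation was tested.

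LAMA3 was lower in the libraries labelled pdna than in those labelled Ti. With the hypoxia list as a covariate its log2 fold change went from -0.61 (SE 0.16) to -0.35 (SE 0.14). This was still below 0 by more than 2 SE (adjusted p = 0.124 by edgeR's quasi-likelihood test). The list's mean level was 0.77 to 0.97 in Ti and -0.87 and -0.96 in pdna replicates 1 and 2. Within groups it differed mainly in pdna replicate 3 and blank replicate 3. The covariate therefore cannot separate that shared state from the group. Exchanged labels may account for the lower LAMA3 level and remain open. The mean of the metallothionein and zinc export list, whose metallothionein genes zinc induces, was lower in the pdna library in 9 of 9 pairs of a pdna and a Ti library. But the smallest gap was 0.000265 against an SD of 0.195 in Ti. Single members did not all follow: MT1X had an FPKM of 46.0 in pdna replicate 3 against 34.9 to 42.2 in Ti. With the covariate the list's median was -0.044 and it did not pass, which decides nothing, since the covariate cannot separate that state from the group. The interferon list, which foreign DNA can induce, was higher in the libraries labelled pdna than in Ti (0.60) and in blank (0.86). This is the direction of the labels as given. Its mean log2 level was 0.62 in pdna, -0.082 in Ti and -0.53 in blank. LAMA3 and the metallothionein list were instead highest in the libraries labelled Ti. LAMA3 was higher in Ti than in blank by 1.08 on the log2 scale (SE 0.16). The metallothionein list had mean log2 levels of 0.68 (SD 0.19) in Ti, -0.31 (SD 0.71) in pdna and -0.36 (SD 0.65) in blank. Plasmid and endogenous transcripts cannot be told apart, because the count table has 1 row for LAMA3, and an effect of the coating itself, the biological explanation the design gives, was not tested.

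The type I interferon list was higher in the libraries labelled pdna than in those labelled Ti. RNA from leukocytes would raise leukocyte markers, whose median log2 fold change was -0.24 (SD 0.34, 5 of 10 markers tested). The most abundant of them, CD68, had 33.4 CPM in pdna and 49.97 CPM in Ti. The other tested markers had group means of at most 3.46 CPM, so they give no sign of leukocyte RNA but test it weakly. The labels name no cells other than HaCaT. With the hypoxia list as a covariate the interferon median was 0.79 (SD 0.75), against 0.60 without it. The list passed camera with the preset correlation but not with an estimated one (adjusted p = 0.135). At a hypoxia level of 0.86, inside the Ti range of 0.77 to 0.97, pdna replicate 3 had an interferon level of 0.54. The Ti libraries had -0.13 to -0.021. At hypoxia levels of -0.87 and -0.96, pdna replicates 1 and 2 had 0.62 and 0.69. These values argue against that state as the whole cause, though the match at the Ti level rests on 1 library. A smaller share of it cannot be told apart. A response of the cells to plasmid DNA may be a further explanation, and was not tested. The cytosolic DNA sensing list had a median of 0.082, but levels of these transcripts do not show whether the sensors were active.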

How the results depend on the processing

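The 7 libraries, sample weights, GC removal, covariate, robust and bias-adjusted edgeR and NewGene alternatives were chosen after seeing the data, and where a value below changed the cause was not tested. Changed genes in pdna against Ti, 0 with 9 libraries, numbered 64 with DESeq2, 1 with limma-voom, 14 with only the groups compared, 2 with log2(FPKM + 0.1), 1 with log2(FPKM + 1) unfiltered, 929 in the 7 libraries, 1889 with sample weights, 15 with the GC trend removed and 2 with the hypoxia list as a covariate. In pdna against blank they numbered 64 with DESeq2, 0 with only the groups compared, 17 with the replicate block, 91 in the 7 libraries, 767 with sample weights, 40 with the GC trend removed, 36 with the covariate and 2 for a fold over 1.5. In Ti against blank they numbered 279 with DESeq2, 17 with limma-voom, 23 with the replicate block, 21 with log2(FPKM + 1) unfiltered, 1705 in the 7 libraries, 2718 with sample weights, 17 with the bias-adjusted deviance, 345 with the GC trend removed, 1404 with the covariate and 1 for a fold over 1.5. Genes changed the same way numbered 13 with DESeq2, 41 in the 7 libraries, 203 with sample weights and 8 with the GC trend removed. Lists passing in pdna against Ti numbered 7 with the covariate, 2 with an estimated correlation and 2 with fry. In pdna against blank they numbered 2 with an estimated correlation and 3 with fry. In Ti against blank they numbered 8 with the covariate, 4 with an estimated correlation and 8 with fry. DESeq2 gave no list test. Leaving out 1 library at a time gave 0 to 50, 0 to 24 and 0 to 63 changed genes in these comparisons, 14 to 19, 9 to 20 and 13 to 22 lists, and 0 to 12 genes changed the same way. LAMA3 had a log2 fold change of -0.81 (adjusted p = 8.47e-05) in the 7 libraries and -0.81 (adjusted p = 3.12e-05) with sample weights in pdna against Ti, and 0.30 (adjusted p = 0.0369) with sample weights in pdna against blank. In Ti against blank it passed at 1.05 with library size alone, 1.08 without a filter, 1.08 with the stricter filter, 1.07 with DESeq2, 1.08 with limma-voom, 1.08 with only the groups compared, 1.09 with the replicate block, 1.09 in the 7 libraries, 1.11 with sample weights, 1.08 with the bias-adjusted deviance, 1.10 with NewGene rows, 1.01 with the GC trend removed and 0.75 with the covariate. Leaving out 1 library, it ranged from -0.80 to -0.49, 0.27 to 0.58 and 1.05 to 1.09. Its adjusted p over these settings and those that leave out 1 library ranged from 3.12e-05 to 1, 0.0369 to 1 and 1.72e-06 to 0.343. Over all settings, values of named genes kept their direction and their side of the threshold 1338, 874 and 1171 times in these comparisons, passed anew 143, 62 and 129 times and no longer passed 0, 83 and 75 times. Lists that passed kept their call 442, 409 and 472 times and lost it 74, 77 and 95 times.

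With the hypoxia list as a covariate the sign changed in 16 of 54 named genes in pdna against Ti, 4 of 38 in pdna against blank and 14 of 50 in Ti against blank. The direction of the test changed in 5 of 18, 1 of 17 and 7 of 20 lists. The covariate is the mean of the hypoxia list itself, so the values of that list and of its members CA9, EGLN3, BNIP3, LDHA and NDRG1 follow from its construction and say nothing about those results. Outside that list the sign changed in 12 of 48, 4 of 38 and 9 of 44 genes and the direction in 4 of 17, 0 of 16 and 6 of 19 lists. In pdna against Ti the genes were MT1X 0.42, CA9 0.074, EGLN3 0.73, BNIP3 0.34, LDHA 0.31, INSIG1 -0.059, KLF6 0.38, MMP7 0.0030, RPL23 0.17, ITGA6 0.50, DST 0.026, SLC30A1 0.75, P2RX5-TAX1BP3 -0.15, TCAF2 0.35, DSG3 0.59 and FDFT1 -0.12. The list medians there were metallothionein and zinc export -0.044, desmosome and adherens junction 0.14, keratinocyte differentiation and cornified envelope -0.21, hypoxia and glycolysis -0.093 and cholesterol synthesis -0.19. In pdna against blank the genes were ITGB4 0.090, PLEC 0.089, MT2A -0.16 and SLC30A1 -0.011, and the list median was hypoxia and glycolysis -0.035. In Ti against blank the genes were CA9 -0.18, NDRG1 -0.20, BNIP3 -0.22, EGLN3 -1.57, LDHA -0.45, MT1X -1.04, MT1E -0.30, FOS -0.56, SLC30A1 -0.76, SERPINB2 -0.86, MMP7 -0.86, F3 -0.16, PTGS2 -1.17 and DSC2 -0.61. The list medians there were metallothionein and zinc export -0.30, desmosome and adherens junction -0.12, keratinocyte differentiation and cornified envelope 0.010, NRF2 oxidative stress 0.12, hypoxia and glycolysis 0.10, ribosomal protein 0.0095 and replication-dependent histone -0.29.

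Other settings changed signs too. In pdna against Ti the changed values were, with library size alone ITGA6 0.025, and with sample weights the DNA replication list 0.031. In pdna against blank they were, in the 7 libraries LAMB3 -0.21, CD151 -0.13, MT2A -0.18 and the medians of the hypoxia and glycolysis -0.029, laminin-332 and hemidesmosome -0.070 and simple epithelial keratin -0.12 lists, and with sample weights LAMB3 -0.15, CD151 -0.078, MT2A -0.0089 and the medians of the laminin-332 -0.016 and simple epithelial keratin -0.14 lists, and with limma-voom ITGB4 0.056, PLEC 0.014 and MT2A -0.011. With the replicate block it was ITGB4 0.0086, and with log2(FPKM + 1) ITGB4 0.081 and PLEC 0.044, and with log2(FPKM + 0.1) ITGB4 0.084 and PLEC 0.051. They were also, with log2(FPKM + 1) unfiltered ITGB4 0.081 and PLEC 0.044, and with the GC trend removed CD151 -0.037, MT2A -0.028 and the simple epithelial keratin median -0.046. The keratin and laminin-332 tests kept their direction. In Ti against blank they were, in the 7 libraries ITGA6 0.21 and PLEC -0.059, and with sample weights ITGA6 0.25, and with the GC trend removed ITGA6 0.0097. Leaving out 1 library at a time turned the sign of further values. In pdna against Ti the ranges were ITGA6 from -0.27 to 0.13, DSG3 from -0.43 to 0.054, the DNA replication list from -0.19 to 0.0065 and the cholesterol synthesis list from -0.018 to 0.19. In pdna against blank the ranges were LAMB3 from -0.18 to 0.25, ITGA6 from -0.37 to 0.19, ITGB4 from -0.36 to 0.24, PLEC from -0.38 to 0.16, CD151 from -0.22 to 0.20, MT1E from -0.76 to 0.47, MT1X from -1.39 to 0.83, MT2A from -0.45 to 0.31, SLC30A1 from -0.35 to 0.79, the simple epithelial keratin list from -0.17 to 0.15, the other basement membrane list from -0.035 to 0.43 and the hypoxia and glycolysis list from -0.46 to 0.84. In Ti against blank the ranges were ITGA6 from -0.25 to 0.21, PLEC from -0.059 to 0.48, SLC30A1 from -0.064 to 0.98, SERPINB2 from -0.19 to 0.81, MMP7 from -0.0048 to 0.90 and PTGS2 from -0.045 to 1.55. The replicate block changed no other call among the lists and lost no other named gene than those given with the comparisons, while BST2 (1.81), SCGB1A1 (-2.39), OLFM4 (-1.47) and MMP13 (-1.42) in pdna against blank and ITGA5 (2.14) in Ti against blank passed under it. Depth was similar in all libraries, and the spread between libraries, not counting, limited the calls.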

Other observations

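The lists of secretory genes and of MHC class II genes were written after some of their members had been seen, and those members were left out of the lists tested here, except PIGR, which the rule for named genes had already named as lower in pdna than in blank. The tests without PIGR, without blank replicate 3, in the 7 libraries, of simulated groups and of class II genes against blank were chosen only after results they bear on were seen. Transcripts of secretory and mucosal epithelium were lower in the libraries labelled Ti and in those labelled pdna than in the same 3 blank libraries, so the 2 comparisons are not independent. Of 24 such genes 15 were tested, and their median log2 fold change was -0.37 (SD 0.51) in pdna against blank (14 of 15 below 0, camera with an estimated correlation, p = 0.00268) and -0.38 (SD 0.58) in Ti against blank (12 of 15 below 0, p = 0.0164). Over all genes 0 members passed in either, and adjusted over the list alone 0 and 1 did. Without PIGR the medians of the other 14 were -0.36 (camera of limma with an estimated correlation, p = 0.00611) and -0.32 (p = 0.0330). Without blank replicate 3 the medians were -0.41 (camera of limma with an estimated correlation, p = 0.0282) and -0.36 (SD 0.60, p = 0.0303), which argues against that library as the whole cause, while in the 7 libraries pdna against blank passed (-0.44, p = 0.0251) and Ti against blank did not (-0.36, p = 0.0993). In both comparisons 13 of 15 members had the same sign, against a mean of 10.1 and at most 14 in 20 simulations of unchanged groups around shared blank libraries. Members below 0 in both numbered 12, against a mean of 5.2 and at most 10, and the covariance of the fold changes was 0.23 against a mean of 0.059 and at most 0.14. The count of equal signs thus lay within the simulated range and the other measures above it, which a change of the blank libraries alone would also give. The simulations drew each gene on its own, without the GC trends of the real libraries or a shared movement of genes. Values above their range may come from these too, so they do not decide the question. AGR2, a protein disulfide isomerase of mucus-secreting cells, had 28.8 ± 16.4 CPM in blank, 14.8 ± 1.35 CPM in pdna and 7.53 ± 0.55 CPM in Ti. Its log2 fold change in pdna against blank was -0.96 (SE 0.33), and -0.39 without blank replicate 3. S100P had -1.22 (SE 0.47) there, with -0.66 without blank replicate 3 and -1.86 without pdna replicate 3. PIGR had -0.93 (SE 0.27) in Ti against blank, and these genes were chosen after their values were seen. A wider fall of such transcripts may account for the list medians, as a hypothesis, and a level particular to the blank libraries is not excluded.

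MHC class II genes other than CD74 and CIITA were higher in the libraries labelled pdna than in those labelled Ti, with a median log2 fold change of 0.73 (SD 0.66) over 10 of 11 genes tested, 9 of them above 0 (camera with an estimated correlation, p = 0.00161). Over all genes 0 of them passed, and 3 did when adjusted over the list alone. HLA-DRA had 6.71 ± 0.294 CPM in pdna and 2.97 ± 0.402 CPM in Ti (1.18, SE 0.28) and HLA-DMB had 1.20 (SE 0.36). CIITA, the transactivator of these genes, had 16.2 ± 0.886 CPM and 9.16 ± 0.310 CPM (0.82, SE 0.15). The list was lower in Ti than in blank (-0.90, camera of limma with an estimated correlation, p = 0.00692), though not past the threshold in the 7 libraries (-0.69, p = 0.0991). In pdna against blank it did not pass (-0.10, SD 0.41, camera of limma with an estimated correlation, p = 0.997). CD74 had -0.088 (SE 0.17) in that comparison, against -1.68 (SE 0.18) in Ti against blank. These values argue against a level of the pdna libraries above blank, and are in line with a lower level of the class II genes and CD74 in the Ti libraries, as a hypothesis. HLA-DRB1 and HLA-DRB5 share reads, and all genes of this paragraph except CD74 were chosen after their values were seen.

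For each comparison of 3 libraries with 3, the 10 splits of the 6 libraries are too few for a share under 0.05. Changed genes numbered 0 in pdna against Ti (highest other split 0, 10 splits as large), 11 in pdna against blank (highest other 0, 1 split as large) and 11 in Ti against blank (highest other 0, 1 split as large). Passing lists numbered 18 (highest other 19, 2 splits as large), 17 (highest other 12, 1 as large) and 20 (highest other 16, 1 as large). Among the 4 splits of the pdna and blank libraries that part every replicate number, the others reached at most 0 genes and 12 lists. For genes changed the same way in pdna against both Ti and blank, the real value of 0 was reached by 100 of 100 splits drawn from 840, and the highest other was 2. Every split reaches a count of 0, so neither this count nor that of 0 changed genes in pdna against Ti bears on chance.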
